A study of Drosophila melanogaster with 3 samples.

How the data were processed

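FMRP, the fly fragile X protein, is an RNA-binding protein, and its RNA contacts were mapped by enhanced CLIP in adult Drosophila melanogaster. In this assay ultraviolet light links protein to RNA, the protein is pulled down, and the linked RNA is sequenced beside a size-matched input from the same kind of lysate. Per the labels, the series has 3 libraries from whole animals: 1 size-matched input and 2 immunoprecipitates of FMRP on FLAG beads. The labels give the cell type of the input as all cells and that of the immunoprecipitates as intestinal progenitor cells, the stem cells and their undifferentiated daughters in the gut. They do not say how FMRP was tagged or in which cells the tagged protein was made.

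The values used here are 2 lists deposited by the authors for the whole series. The first holds 60497 sites, each 1 nt wide with a strand, a constant state and a score. The second holds 1829 target gene names with no measurement. The score is the authors' own value per site, deposited without a stated unit. The submitters' processing notes name cutadapt 2.9, UMI-tools, STAR 2.7.3a, SAMtools 1.10 and DESeq2, with no role or order. The site caller, the genome build, the annotation, whether the immunoprecipitates were pooled, how the input entered the score, and the rule that turned sites into targets are not given in the sources used here. The authors' name for the site list holds the term INnorm, which may mean normalised to the input, but the way is not stated. No values per library were used, so depth is unknown, no difference between libraries could be tested, and no interval reflects variation between animals or libraries. Scores served only to describe and rank sites within the list.

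Gene names were matched to an NCBI RefSeq gene table of Drosophila Release 6. Of the target names, 1753 matched a current symbol, 65 matched the synonym of a single gene, and 11 with several possible matches were settled by locus tag. The build of the site list was settled from the data. With sites as deposited, 1823 target genes on chromosomes 2L, 2R, 3L, 3R, 4 and X held a site within their span, against 458 and 457 after moving all sites by 100000 nt in either direction. Coordinates below are those of the site list, counted from 1, and gene boundaries are not printed because the list names no build.

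The gene table gives spans without strand or exons. A site in the gene of a small RNA was given to the smallest such gene. Any other site was given to a gene if it lay in exactly 1 span, and otherwise to none. This rule was chosen after seeing the files. It assigned 54042 sites (89.3%), left 4216 in several spans unassigned, and left 1106 sites of the main chromosomes in no span. As a check, 1382 of the 1444 genes with at least 5 assigned sites (95.7%) had all of them on 1 strand. Whether that is the gene's own strand could not be checked. Among genes named below, mask, nej, pAbp, zip, Ptp61F and unc-13 had sites on both strands, so part of each count is not on the gene's strand. Introns, exons, untranslated regions and base sequence were not analysed here, so the planned results on transcript regions and short sequence words were not run. Genomic span replaced exonic length, and overlap of any spans replaced overlap on the same strand.

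The gene lists, main tests, naming rule and part of the alternatives were fixed before the data were examined. Tests and alternatives chosen after seeing the data are named as such below. Each of 28 gene lists was compared with all 13959 protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The plan was to use genes with a site as background if every target held one. All protein-coding genes were used instead, because a few targets held no site, of which only Adk2 was protein-coding. This choice matters: 19 lists had a higher share of targets with it, and 1 with protein-coding genes that have a site. The background includes genes not expressed in adult flies, since expression was not used here. As an alternative fixed beforehand, 10000 random lists matched on genomic span in 20 bins gave a two-sided p, whose smallest possible value is 0.0002. These tests treat genes as units, and genes are not replicates. Differences of medians between target and other genes used two-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only and, for shares of sites, treat neighbouring sites as independent. A threshold of 0.05 was used throughout.

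The list test was tested on simulated data: target labels for the 13959 genes were drawn in 20 simulations with the real dependence on span, with lists of 25 genes. Fisher's exact test called 78% of lists planted with an odds ratio of 6, 1.75% of random lists and 49% of lists of long genes with nothing planted. The span-matched test called 63%, 0.5% and 0% of them. Apart from the planted lists, labels depended only on the same span bins that this test uses. Its control of long genes was therefore built in, and no dependence on expression was simulated. Span-matched values therefore stand beside the calls.

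Genes were named by a fixed rule: Fmr1, the 12 targets with most assigned sites (ties by total score, then name), up to 4 targets with most assigned sites in each list, and all genes of a list of FMRP targets named in earlier fly work. A part of the rule that took the top targets by the authors' measure was void because the target list has none. Not every gene that the rule takes is reported here. Other genes named were chosen after their values were seen. Alternatives covered the background, span, overlapping genes, the definition of a target, the score threshold, merging of sites within 20 or 50 nt (the merged site took the highest score), the 10 genes with most sites, mitochondrial genes and ribosomal RNA, and a flank of 500 nt. Comparisons of chromosomes, RNA classes, positions in tRNA genes and pooled cell types were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.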

Results

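FMRP contacts in adult flies were described by 60497 sites, of which 28056 lay on the plus strand and 32441 on the minus strand. Chromosome 3R held 14730 sites, X held 11391, 2R held 10785, 3L held 10518, 2L held 9176 and the small chromosome 4 held 2325. The median of the authors' score was 2.78, with quartiles of 1.08 and 6.39. Protein-coding genes made up 1560 of the 1829 target genes (a further 269 were non-coding). The libraries behind both lists were 2 FMRP immunoprecipitates and 1 size-matched input, and their depth is unknown.

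Which RNAs carried the most FMRP sites was read from the number of sites assigned to each gene. shot, which encodes a giant linker of actin and microtubules, led with 552 sites between 13864486 and 13925463 on 2R. Tet, the fly homologue of the TET dioxygenases, followed with 514 sites and a median score of 7.80. Msp300, a giant nesprin that joins nuclei to the cytoskeleton, had 469, the transcriptional regulator spen had 468, and the chromatin remodeller kis had 446. Next came the zinc finger homeobox gene zfh2 with 408, the RNA-binding protein gene Syp with 342, mask with 326, mamo with 320 and the ubiquitin-conjugating enzyme gene Bruce with 317. hdc, known for its restricted expression in imaginal and progenitor cells, had 313, and Unr, an RNA-binding translational regulator, had 300.

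Sites were concentrated in few genes. The 10 genes with most sites held 7.70% of assigned sites, and the 100 with most held 36.0% (95% interval 35.6 to 36.4). The median target had 11 sites, with quartiles of 4 and 30, and 122 targets had at least 100. Sites also lay close together: the median distance to the next site in a gene was 1 nt, and 50.9% of sites were followed by one on the next base. Random positions in the same spans gave a mean median distance of 105 nt and 1.15% on the next base, over 100 placements. The random positions included introns.

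**Figure D1:**
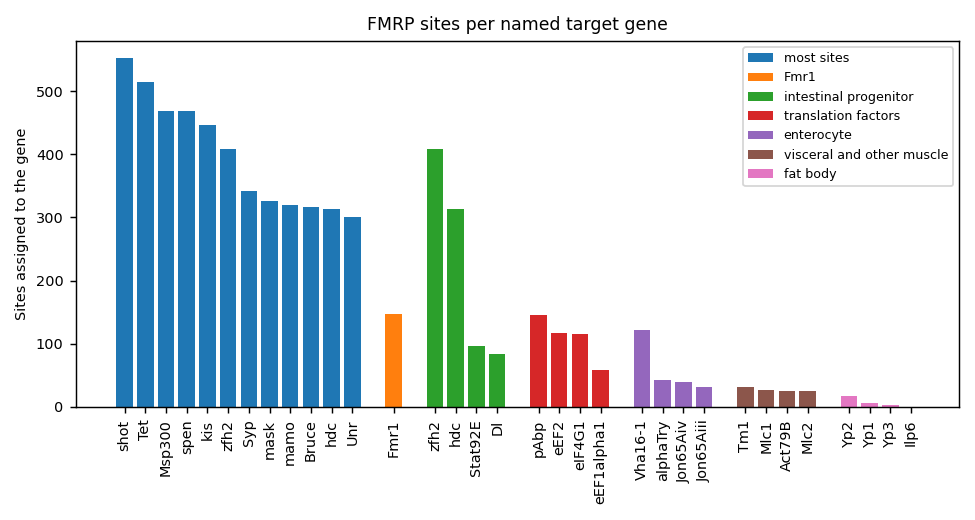
Number of sites assigned to each named target gene, grouped by the part of the naming rule that chose it; zfh2 and hdc appear both among the genes with most sites and among intestinal progenitor genes. Bars run from 552 sites in shot to 0 in Ilp6, whose 6 sites in span lie in overlapping genes and were not assigned.

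Fmr1, the gene of FMRP itself, was a target with 147 sites between 10103260 and 10108749 on 3R, all on the minus strand. Its median score was 7.78 and its highest 81.6. RNA of the endogenous gene and of a tagged transgene cannot be separated in these lists. Of 9 genes on a list of FMRP targets named in earlier fly work, 7 were targets, with Fmr1 itself counted among them. The cell polarity gene l(2)gl had 183 sites, the calmodulin-binding protein gene poe 174, the profilin gene chic 67, the MAP1B homologue futsch 41, the neuronal adhesion gene Dscam1 18 and the small GTPase gene Rac1 6. The sodium channel gene ppk and the ubiquitin ligase gene Cbl had 0 sites and were not targets. The odds ratio of the list was 27.9 (adjusted p = 1.61e-05, Fisher's exact test), and its count was 3.31 times that of span-matched lists (adjusted p = 0.00498). The list did not pass against members of all the fixed lists (odds ratio 5.58, adjusted p = 0.0903, Fisher's exact test). Among genes with a site all 7 of its 7 members were targets, so it could not score higher, and it did not pass (adjusted p = 0.314, Fisher's exact test). Without overlapping genes it had 4 targets of 6, again 3.31 times span-matched lists, and did not pass (adjusted p = 0.0743).

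Target and site lists were compared as products of successive steps. Of the 1829 targets, 1825 held a site in their span (99.78%, 95% interval 99.44 to 99.94). The 4 without one were the tRNA genes tRNA:Glu-CTC-2-1, tRNA:Glu-CTC-3-4 and tRNA:Asp-GTC-1-10 and the protein-coding gene Adk2. In the other direction, 2714 genes had a site in their span and 67.2% of them were targets (65.4 to 69.0). Of the 889 other genes with a site, 339 had 1. Among assigned sites, 52140 (96.5%) fell in targets and 1902 in other genes. The chromatin protein gene mod(mdg4), with 31 sites, and Apc, a negative regulator of Wnt signalling, with 13, were not on the target list.

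Intestinal progenitor genes were the list with the highest share of targets, 12 of 15 (80.0%, 95% interval 51.9 to 95.7). zfh2 had 408 sites, hdc 313, Stat92E, the JAK-STAT transcription factor, 97 and the Notch ligand gene Dl 83. The stem cell transcription factor gene esg, named after its value was seen, had 77 with a median score of 23.3. Su(H), klu and N were not targets. Of these genes, 8 members and 6 targets are also on the Notch or JAK-STAT lists: Dl, Stat92E, spdo, E(spl)mbeta-HLH, E(spl)malpha-BFM and E(spl)m3-HLH among the targets, and N and Su(H). The odds ratio was 32.03 against all protein-coding genes (adjusted p = 8.42e-09, Fisher's exact test). The count was 4.44 times that of span-matched lists (adjusted p = 0.00112), and the odds ratio was 6.49 against the members of all the fixed lists (adjusted p = 0.0169), an alternative chosen after seeing the data. With only genes that have a site as background, the odds ratio was 2.84 (adjusted p = 0.417).

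Genes listed for other cell types of the whole animal were also on the target list. Whether progenitors express them too was not examined. Enterocyte genes had 7 targets of 18 (odds ratio 5.08, adjusted p = 0.0033; 3.74 times span-matched lists, adjusted p = 0.0042), among them the proton pump gene Vha16-1 with 121 sites and the digestive protease genes alphaTry with 43, Jon65Aiv with 39 and Jon65Aiii with 32. Close protease paralogues can share reads, so these counts are uncertain. Muscle genes had 9 of 20 (odds ratio 6.53, adjusted p = 0.000304; 2.19 times, adjusted p = 0.0312), led by Tm1 with 31 sites, Mlc1 with 27, Act79B with 26 and Mlc2 with 25. Germline and ovary genes had 8 of 19 (odds ratio 5.81, adjusted p = 0.00102; 3.11 times, adjusted p = 0.00653), with the eggshell genes Vm26Aa at 16, Cp16 at 15 and Cp15 at 9 sites and the germ plasm gene tud at 14. With genes of at least 1 site as targets, the odds ratio of germline genes was 2.86 (adjusted p = 0.0519). Muscle genes did not pass against span-matched lists once overlapping genes were left out (adjusted p = 0.261). They then had 5 targets of 12, and the ratio was 2.01, against 2.19 with all members. Against members of all the fixed lists, the odds ratios of these lists were 0.992, 1.29 and 1.14, with adjusted p of 1, 0.752 and 0.877.

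Several other cell type lists did not pass the test. Fat body genes had 4 targets of 16 (adjusted p = 0.121), the yolk protein genes Yp2 with 18 sites, Yp1 with 6 and Yp3 with 3, and Ilp6. Enteroendocrine genes had 3 of 17 (adjusted p = 0.479): pros with 85 sites, IA-2 with 9 and Dh31 with 1. Glial genes had 2 of 9 (adjusted p = 0.324), Gs2 with 13 sites and moody, whose 74 sites in span all lie in overlapping genes. Testis genes had 1 of 15 (adjusted p = 1), Mst84Da with 8 sites. Haemocyte genes had 0 of 9 (95% interval 0 to 33.6%, adjusted p = 0.657). Neuronal genes had 6 of 20 (odds ratio 3.42, adjusted p = 0.0263), with futsch at 41 sites, unc-13 at 35, Dscam1 at 18 and Csp at 3, but span-matched lists gave as many (ratio 0.989, adjusted p = 1). futsch and Dscam1 are also on the list of earlier targets.

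Progenitor genes and other cell types were then set against each other, a comparison added after seeing the data. Progenitor genes had 12 targets of 15 and the pooled genes of 8 other cell types, without enteroendocrine genes, 37 of 126 (29.4%, 95% interval 21.6 to 38.1). The odds ratio between them was 9.62 (p = 0.000208, Fisher's exact test, two-sided). With enteroendocrine genes added to the pool, 40 of 143 were targets and the odds ratio was 10.3 (p = 0.000118, Fisher's exact test). The median number of sites in the span was 44.5 in the progenitor targets and 21 in the 37 others. No progenitor target was near 44.5, which falls in the gap between Sox21a with 12 sites and esg with 77. The difference of median log2(sites + 1) was 0.53 and did not pass (p = 0.253, two-sided permutation test). The p-values that follow here are for the same measure. Counts in the span include sites shared with overlapping genes and were not adjusted for gene length. Among targets with at least 1 assigned site the medians were 44.5 and 17.5 (p = 0.12, permutation test). They were 11.5 and 14 (p = 0.758, permutation test) only when targets whose sites all lie in overlapping genes, such as mira with 82 sites in its span, were counted as 0.

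**Figure D2:**
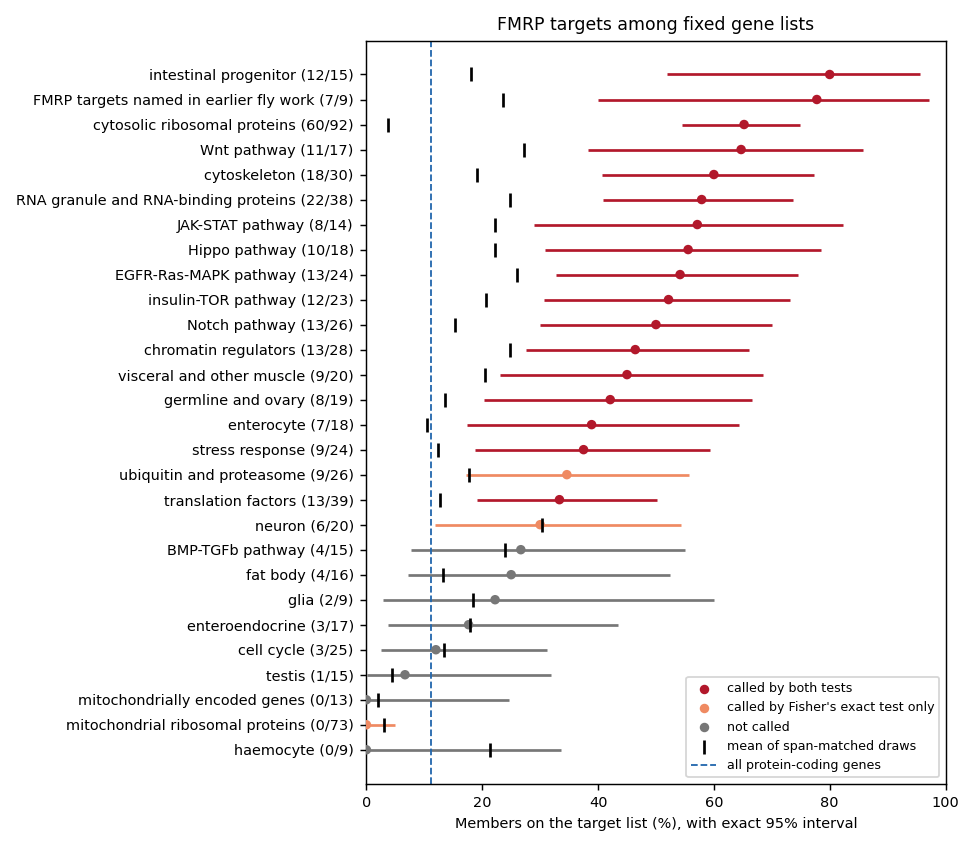
Share of each gene list on the target list, with the exact 95% interval as a line, the number of targets and members in brackets, the mean of span-matched random lists as a black tick and the share among all protein-coding genes (11.2%) as a dashed line. Intestinal progenitor genes reach 80.0%, cytosolic ribosomal proteins 65.2%, and mitochondrial ribosomal proteins 0%.

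mRNAs of the translation machinery were among the targets. Cytosolic ribosomal protein genes had 60 targets of 92 (65.2%, 95% interval 54.6 to 74.9), with an odds ratio of 15.5 (adjusted p = 1.24e-33, Fisher's exact test). That was 17.8 times the count of span-matched lists, whose mean was 3.38 (adjusted p = 0.00112). Against members of all the fixed lists the odds ratio was lower, 3.49 (adjusted p = 9.31e-07, Fisher's exact test). The count was then 2.09 times that of span-matched lists from that background (adjusted p = 0.0028). Abundance of these mRNAs was not used here. RpS7 had 42 sites, RpL3 39 and RpS5a 36. Translation factor genes had 13 of 39 (odds ratio 3.999, adjusted p = 0.000399; 2.61 times, adjusted p = 0.0040), led by the poly(A)-binding protein gene pAbp with 145 sites, eEF2 with 117, eIF4G1 with 115 and eEF1alpha1 with 59. Against members of all the fixed lists the odds ratio of translation factor genes was 0.768 (adjusted p = 0.611). Mitochondrial ribosomal protein genes had 0 of 73 (95% interval 0 to 4.93%), lower than the background by Fisher's exact test (adjusted p = 0.00051). They were not lower than span-matched lists, whose mean was 2.22 targets (adjusted p = 0.284). Against members of all the fixed lists they were lower (adjusted p = 3.81e-16, Fisher's exact test). Span-matched lists from that background had a mean of 17.8 targets, and the mitochondrial list was lower there too (adjusted p = 0.0028). Several ribosomal protein genes host snoRNAs or have paralogues, so their site counts are uncertain.

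Genes of RNA granules and RNA-binding proteins had 22 targets of 38 (57.9%, 95% interval 40.8 to 73.7). Syp had 342 sites, the CCR4-NOT scaffold gene Not1 263, the Argonaute gene AGO1 248 and the hnRNP gene sqd 201. The odds ratio was 11.1 (adjusted p = 5.29e-11), and the count was 2.33 times that of span-matched lists (adjusted p = 0.00112). Cytoskeletal genes had 18 of 30 (odds ratio 12.05, adjusted p = 1.45e-09; 3.15 times, adjusted p = 0.00112). Besides shot and Msp300, the myosin heavy chain gene zip had 134 sites and the actin gene Act5C 95. Fmr1 is counted in the RNA granule list, and chic, Rac1 and futsch in the cytoskeletal list, so both share targets with the list of earlier targets.

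Signalling pathways with a place in intestinal stem cell control were tested in turn. Wnt pathway genes had 11 targets of 17 (odds ratio 14.7, adjusted p = 1.20e-06), with the receptor gene fz2 at 75 sites, dco at 40, lgs at 29 and arr at 19. JAK-STAT genes had 8 of 14 (odds ratio 10.6, adjusted p = 9.00e-05), with Stat92E at 97, Ptp61F at 29, Socs16D at 18 and ken at 17. Hippo genes had 10 of 18 (odds ratio 9.99, adjusted p = 1.55e-05), with msn at 193, kibra at 64, Tao at 25 and ex at 23. EGFR-Ras-MAPK genes had 13 of 24 (odds ratio 9.46, adjusted p = 1.43e-06), with the repressor gene cic at 229, sty at 170, Egfr at 136 and S at 118. Insulin-TOR genes had 12 of 23 (odds ratio 8.73, adjusted p = 5.29e-06), with Pi3K21B at 91, foxo at 84, Akt1 at 76 and REPTOR at 64. Notch genes had 13 of 26 (odds ratio 8.01, adjusted p = 4.13e-06), with nej at 167, Dl at 83, and gro and H at 38 each. BMP-TGFb genes had 4 of 15 (adjusted p = 0.104): shn at 198, Smox at 58, babo at 40 and Med at 4. Apart from BMP-TGFb, the pathways had between 2.09 and 3.26 times the targets of span-matched lists, with adjusted p from 0.00112 to 0.0161. Against members of all the fixed lists, none of them passed (the lowest adjusted p was 0.105, for Wnt).

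Chromatin regulators had 13 targets of 28 (odds ratio 6.94, adjusted p = 9.32e-06; 1.87 times span-matched lists, adjusted p = 0.0313), with kis at 446 sites, the BAP complex gene osa at 206, nej at 167 and dom at 131. Against members of all the fixed lists the odds ratio of chromatin regulators was 1.37 (adjusted p = 0.607, Fisher's exact test). Without overlapping genes they had 1.91 times the targets of span-matched lists and did not pass (adjusted p = 0.244). Stress response genes had 9 of 24 (odds ratio 4.79, adjusted p = 0.0012; 3.05 times, adjusted p = 0.00504), with the chaperone genes Hsc70-4 at 57 and Hsp83 at 36, the Fos homologue kay at 29 and Xbp1 at 27. Without overlapping genes the stress response list did not pass (odds ratio 3.47, adjusted p = 0.0766), and against members of all the fixed lists its odds ratio was 0.933 (adjusted p = 1). Ubiquitin and proteasome genes had 9 of 26 (odds ratio 4.23, adjusted p = 0.00219), with the ubiquitin ligase genes hyd at 249, ctrip at 174 and poe at 174 and the deubiquitinase gene puf at 198. Their count did not pass against span-matched lists (ratio 1.96, adjusted p = 0.0728), and against members of all the fixed lists the odds ratio was 0.819 (adjusted p = 0.77). Cell cycle genes had 3 of 25 (odds ratio 1.08, adjusted p = 0.782): E2f1 with 75 sites, CycD with 9 and Dp with 5. Against members of all the fixed lists their odds ratio was 0.203 (adjusted p = 0.0305, Fisher's exact test). With span-matched lists drawn from that background the difference did not pass (ratio 0.351, adjusted p = 0.0784). Mitochondrially encoded genes had 0 of 13 (adjusted p = 0.449), whereas 8 of the 13 had a site, and with genes of at least 1 site as targets the odds ratio was 9.94 (adjusted p = 0.000185).

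Across the 28 lists, 19 had a higher share of targets than all protein-coding genes, and 17 did so against span-matched lists. With overlapping genes left out, 7 lists passed against span-matched lists: intestinal progenitor, cytosolic ribosomal protein, cytoskeletal, enterocyte, germline and ovary, Notch and insulin-TOR genes. The other lists did not. Among them, ratios to span-matched lists with and without overlapping genes were 2.37 and 2.12 for Wnt (adjusted p = 0.302 without them). They were 2.09 and 1.91 for EGFR-Ras-MAPK (0.244), 2.33 and 1.93 for RNA granule (0.0775) and 2.49 and 2.57 for Hippo genes (0.0743). For translation factor genes they were 2.61 and 2.68 (0.0743), and for earlier targets 3.31 and 3.31 (0.0743). Each of these lists had fewer members without overlapping genes, so the losses do not show that overlap made the excess. Against the members of all the fixed lists, 2 remained, intestinal progenitor genes and cytosolic ribosomal proteins.

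Target genes were longer than others. The median genomic span was 7082 nt in the 1560 protein-coding targets and 1944 nt in the 12399 others, a ratio of 3.64 (p = 1e-05, the smallest the permutations can give). The share of targets was 1.15% (95% interval 0.496 to 2.25) among the shortest genes, of 162 to 565 nt, and 32.8% (29.3 to 36.4) among those over 29124 nt. Against only the 734 other protein-coding genes with a site, whose median was 5988 nt, the ratio was 1.18 (p = 0.0151, permutation test).

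Non-coding RNA genes held sites with high scores. Of 290 nuclear tRNA genes, 89 were targets (30.7%, 95% interval 25.4 to 36.3), with a median site score of 12.9. Of 269 snoRNA genes, 94 were targets (34.9%, 29.3 to 41.0), with a median of 8.07, while sites in protein-coding genes had a median of 2.58. Named snoRNA targets included snoRNA:Psi18S-110 and snoRNA:Psi28S-3436b, guides of pseudouridylation with 25 sites each. The snRNA genes had 7 targets of 32, both signal recognition particle RNA genes were targets, and so were the RNA genes of RNase P and RNase MRP. Among the 605 sites from the 99th percentile of the score upwards, 194 lay in tRNA genes and 198 in protein-coding genes. A further 186 were not assigned to any gene, and 21 lay in rRNA pseudogenes. The highest score, 708, was shared by 18 sites, 14 of them in tRNA genes, so it may be a ceiling of the score. Copies of tRNA, snRNA and rRNA genes share reads, so which copy a site belongs to is uncertain.

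Within tRNA genes, sites gathered at a few positions. In 101 tRNA genes of 70 to 75 nt with 532 sites, 35.0% of sites lay at positions 32 to 38, the anticodon loop, against 9.66% after random circular shifts (p = 2e-05, the smallest the two-sided permutation test can give). Within 1 nt of position 58, in the T arm, lay 11.5% against 4.14% (p = 2e-05, permutation test). Sites also lay elsewhere, with 14 at position 19 and 18 at position 46, which were not tested. Positions were counted from the 5' end of the gene, without alignment to a tRNA numbering. Copies of tRNA genes share reads, so the 101 genes are not independent and these p-values may be too small. The shifts also spread sites evenly over the gene, including the 3' end, where few sites lay.

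**Figure D3:**
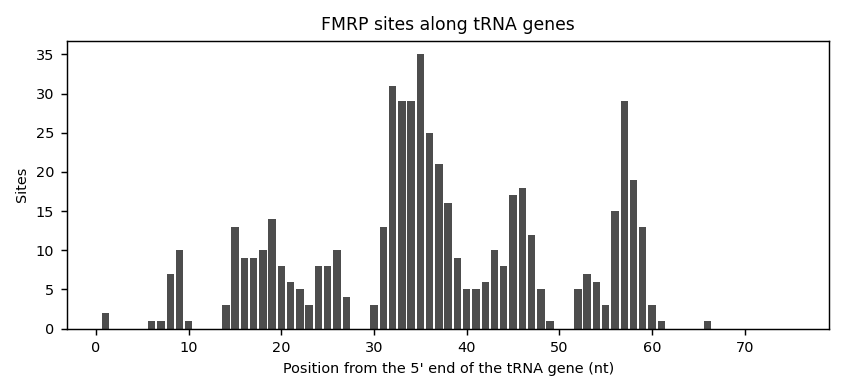
Number of sites at each position of 101 tRNA genes, counted in nt from the 5' end of the gene. Sites gather between positions 32 and 38 (186 of 532) and around position 58 (61 within 1 nt). Other positions hold sites too, such as 45 with 17 and 46 with 18.

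The median score per gene did not separate targets from other genes over all sites, but its quartiles lay further apart in other genes. The median of gene medians was 2.53 in 1614 targets (quartiles 1.69 and 4.19) and 2.62 in 658 other genes (quartiles 0.880 and 8.25), and the difference of -0.0906 did not pass (p = 0.367, two-sided permutation test). The difference of targets from other genes was -2.69 among sites at or above the median score, and turned to 1.41 with sites merged within 50 nt (p = 1e-05 for both, the smallest the permutation test can give). A merged site took the highest score of its sites, which can raise genes with many neighbouring sites, so this turn need not reflect the score itself.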

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

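The tests weighed here were all chosen after the results were seen. Some sites fell outside the nuclear gene spans, and there was no control list to set them against. The mitochondrial genome, of which only the protein-coding genes entered a list comparison, held 419 sites, although none of its genes was on the target list. COX1 had 81 and CYTB 39. Mitochondrial tRNA genes had 111 sites per kb, against 19.3 in mitochondrial protein-coding genes and 19.4 in mitochondrial rRNA. Neighbouring sites are not independent, so no test was made of this difference. The rDNA scaffold held 378 sites, 48 other scaffolds held 755, and 1106 sites of the main chromosomes lay in no gene span.

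Genes of chromosome 4 were on the target list more often than those of the other chromosomes tested. Of 80 protein-coding genes, 35 were targets (43.8%, 95% interval 32.7 to 55.3; odds ratio 6.30, adjusted p = 7.64e-13 over the main chromosomes). Gene span is argued against as the whole cause, since span-matched draws gave a mean of 19.1 targets and the observed count was 1.83 times that (adjusted p = 0.0012). A higher share of genes expressed in adult flies on this chromosome may account for the rest, and expression was not used here. No biological explanation was tested.

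In tRNA genes, where reverse transcription can stop at methylated bases as well as at bases linked to protein, sites gathered at a few positions. The excess within 1 nt of position 58, 11.5% of sites against 4.14% after circular shifts, is what stops at the methylated base of the T arm would give, and protein contact there may give it too. Position 46 held 18 sites and position 19 held 14, so sites were not limited to position 58 and the anticodon loop. Those 2 positions were not tested. Position 37, often methylated too, had 11.7% against 4.14% within 1 nt, but it lies inside the anticodon loop peak, so its excess cannot be separated from that of the loop. Positions 9 and 26 had no excess, with 7.52% against 8.30% (p = 0.675, two-sided permutation test), which neither shows nor excludes stops there. Whether the size-matched input has the same profile stays open, as does what any normalisation to the input removed.

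mRNAs of genes listed for other cell types were on the target list of immunoprecipitates labelled as progenitor cells. Gene span is argued against as the whole cause, since the 37 targets among 126 genes were 1.76 times the mean of span-matched draws (p = 0.0004, a permutation-type test). Carry-over of abundant RNA of the whole animal was taken, after seeing the data, to leave fewer sites per target than in progenitor genes. The difference of median log2(sites + 1) was 0.53 by sites in the span (p = 0.253, permutation test). It was 0.78 in targets with at least 1 assigned site (p = 0.12, permutation test). It turned to -0.26 (p = 0.758, permutation test) only with targets counted as 0 because all their sites lie in overlapping genes. None of these passed. Site counts were not adjusted for gene length, and abundant RNA could also give many sites, so neither sign could settle the question. Carry-over cannot be told apart from FMRP contacts in those other cell types or in progenitors. Levels in the input, and expression of these genes in progenitors, were not used here.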

How the results depend on the processing

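The alternatives with chromosome 4 left out, with all sites in a span counted, with the members of all fixed lists as background, with protein-coding genes only, and the span ratio without overlapping genes were chosen after seeing the data. The number of lists with a higher share of targets, 19 by Fisher's exact test, was 1 with protein-coding genes that have a site as background and 2 with members of all fixed lists. It was 17 without overlapping genes and 18 without chromosome 4. With genes of at least 1 and at least 3 sites as targets it was 19 and 21. These counts need not hold the same lists. Among protein-coding genes with a site 68.0% were targets, so some lists could not pass there even with every member a target. Enterocyte genes (7 of 7) and stress response genes (9 of 9) were such lists. Span matching combined with each setting, also chosen after seeing the data, left 1 and 2 lists with those backgrounds, 7 without overlapping genes, 16 without chromosome 4, and 16 and 14 with the site-based targets. The neuron list fell to a ratio of 0.989 with span matching and to odds ratios of 0.660 against members of all fixed lists, 0.563 among genes with a site and 0 without overlapping genes. Against members of all fixed lists, the odds ratio was 0.203 for cell cycle (adjusted p = 0.0305), 0.992 for enterocyte, 0.933 for stress response, 0.768 for translation factors and 0.819 for ubiquitin and proteasome genes. The cell cycle list did not pass against span-matched lists from that background (adjusted p = 0.0784). Mitochondrially encoded genes rose from 0 to an odds ratio of 9.94 with at least 1 site as the definition of a target and 13.4 with at least 3, since the target list holds none of them while the site list does. The share of sites in the 100 genes with most sites moved from 36.0% to 39.1% at or above the median score, 50.4% at or above the 90th percentile, 34.9% and 33.2% with sites merged within 20 and 50 nt, 32.8% without the 10 top genes, 36.5% without mitochondrial genes and rRNA, 37.3% in targets only and 31.7% with all sites in a span. The difference of score between targets and other genes was -2.69 and -5.87 in the higher-scoring parts, and turned to 0.57 and 1.41 with sites merged within 20 and 50 nt, where the merged site takes the highest score of its sites. Targets with a site within 500 nt of the span came to 99.95%. The cause of the other changes was not tested. The span ratio kept its direction and passed in both alternatives (1.18 and 3.30). Planned results on transcript regions and short sequence words, exonic length, strand of overlap and score by region were not run, for want of exons, strand and sequence. No paired analysis was possible because no values per library were used. Depth is unknown, so a gene without sites cannot be told from one with too little RNA to give any.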

Other observations

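esg, the transcription factor gene that marks intestinal progenitors, stood out by score; these values and all tests in this part were taken after seeing the data. Its 77 sites, between 15333866 and 15335990 on 2L, had a median score of 23.3 and a highest score of 194. Among 924 protein-coding targets with at least 10 sites, whose median was 2.37, it ranked 2, after Pzl with 33.9. Next came cad, a homeobox gene of the hindgut and midgut, with 18.6 over 12 sites and scyl with 15.3 over 136.

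Precursors of microRNAs and host genes of snoRNAs were among the non-coding targets. Of 260 microRNA genes, 11 were targets (4.23%, 95% interval 2.13 to 7.44): mir-1, mir-8, mir-14, mir-34, mir-184, mir-275, mir-276a, mir-277, mir-317, mir-4956 and mir-9370. mir-34, with 3 sites, had a median score of 41.2, and mir-14, also with 3, had 28.4. The snoRNA host genes Uhg1, Uhg2, Uhg3, Uhg4, Uhg5 and Uhg7 were all on the list. Uhg5 had 84 sites in its span and Uhg4 had 61, most of which were assigned to the snoRNA genes within or left unassigned. The minor spliceosome RNA genes snRNA:U11 and snRNA:U4atac had 26 and 18 sites.

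On chromosome 4, zfh2 led with 408 sites, followed by Thd1, a thymine DNA glycosylase gene, with 210, the plexin gene PlexA with 183, MED26 of the Mediator complex with 169 and gw, the GW182 partner of Argonaute, with 123. The share of targets was 14.9% on X, 1.18 times span-matched draws (adjusted p = 0.003), and 8.92% on 2L, 0.849 times (adjusted p = 0.004).

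The highest value of the list, 708, may be a ceiling, since 18 sites share it. It was reached in Pzl, a Piezo-like channel gene with 10 sites, and in tei with 16 sites, of which tei was not on the target list. mrj, with 26 sites, reached 456.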
